A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

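The data were 4 ChIP-chip arrays of Saccharomyces cerevisiae, 2 for TAP-tagged Rpb3 and 2 for TAP-tagged Rpb4, grouped by the labels. Per the labels, cells were fixed with 1% formaldehyde for 20 min, chromatin was sheared to fragments of about 400 to 500 bp, tagged protein was collected on IgG beads, and IP (Cy5) and whole-cell extract (Cy3) DNA were hybridised together to Agilent yeast arrays of 60-nucleotide probes about 290 bp apart. The same dye held the IP on all 4 arrays, so a dye effect does not cancel, and no untagged or mock precipitation was used here as background. All 4 arrays lay on 1 slide, so a slide block could not be fitted.

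Spot intensities came from Agilent Feature Extraction 9.1, per the submitters' processing notes. The deposited files give, per the file headers, foreground and background intensities of each channel, normalized IP and WCE intensities, a log2 ratio, single-array p-values, a neighbourhood score, and flags for excluded probes and bound regions. The columns were tested on the values. The authors' normalized intensity was the foreground minus the local background minus a constant for each array (10, 6, 7.25 and 5), and the WCE channel was then multiplied by one factor for each array (0.690, 0.446, 0.808 and 0.928). The deposited log2 ratio is the log2 of these 2 signals. The software that made these columns and the genome build of the probe positions are not given in the sources used here. The authors' p-value and score columns and bound-region flags were not used here. The deposited series table held the same log2 ratios, equal to 5 decimals for all but 41, 0, 36 and 65 probes of the 4 arrays, which it lists at 0. The medians of its columns were -0.042, -0.005, -0.035 and -0.040, its scale and direction are those of the files, and its rows name no probe. It therefore gave no separate alternative. The plan had named Agilent's processed signals and outlier flags, and the normalized intensities and the exclusion flag took their place.

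Each array had 41775 data probes, and 3444 control spots were left out. Excluded probes (100, 81, 149 and 179) and non-positive signals were set as missing. The median foreground was 72.9 to 126 times the background in the IP channel and 151 to 168 times in the WCE channel, and no probe was saturated. Log2(IP/WCE) was centred on each array's median over data probes, with no loess or quantile step. Probes were tied to genes by the files' own annotation, 30279 of them inside 5493 genes, and 181 lay inside more than 1 gene. The names of 5478 genes were matched to the R64 table of locus tags, used for names only, and the other 15 kept the files' names. Positions are those of the files. Gene length was taken as the span tiled by probes.

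Gene values (means over probes inside the gene) and probe values were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) over all 4 arrays, with coefficients for both groups and their difference. Tests were two-sided and adjusted by Benjamini-Hochberg over all genes or probes at 0.05. The 3' minus 5' difference per gene was fitted the same way. Region means, the relation to gene length and the relation to occupancy were described with the range over the 4 pairings of arrays. Gene lists were tested with camera (preset correlation 0.01), camera with an estimated correlation, and fry. Of 22 lists, 21 were fixed beforehand and the mitochondrial genome was added from the annotation. The pair of tagged loci was too short to test, which left 21. The strain marker list stood at a mean of 1.13 with Rpb3 and 1.11 with Rpb4 (array means 0.73 and 1.49), but the Rpb4 mean rests on TRP1 and HIS3, which that strain lacked in its extract. Over the other 5 genes the mean difference was -0.90. Of its 7 genes 5 were above the median probe in each group, 1 was below with Rpb4, and 3 fell between the groups (camera adjusted p = 0.413 for the difference). The 2 tagged loci had means of 0.88 and 0.44. The 16 mitochondrial genes had means of -1.50 with Rpb3 and 0.18 with Rpb4, where the 2 array means were of opposite sign (-0.88 and 1.23), with 0 of them passing for the difference (limma). For subunits of RNA polymerases I and III, 8 of 19 genes were above the median probe in each group, and 4 and 5 were below. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared the tables and figures.

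The design, the lists, the alternatives and the rule for named genes were set before the data were examined. For each of the 3 comparisons per gene the rule took the 10 genes with the largest positive and the 10 with the largest negative value among those past an adjusted p of 0.05 whose arrays all went the same way, the 2 members of largest and the 1 of smallest value in each list, and always RPB3, RPB4, RPO21, RPB7 and the strain markers. Where fewer than 10 passed, those of smallest p filled the number and were said not to pass, and dubious reading frames overlapping a named one were left out. Some genes under the rule are not reported here. Genes outside the rule are said to have been named after their values were seen.

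The fit was tested on simulated data for the difference over 5490 genes, with 200 changed genes. It recovered 33 of 50 genes changed by a log2 of 0.5, 48 of 50 changed by 1, and all 50 changed by 2 and by 3, with 6 unchanged genes among 187 calls. For the group means, 198 of 200 genes changed by 1 were recovered. The simulated noise was independent between genes and of equal size in both groups. In the data the 2 Rpb3 arrays differed more than the 2 Rpb4 arrays (median per gene 0.140 against 0.035). The simulated rates therefore do not give the error rate of the calls on the data. Alternatives were normexp background correction (offset 50), no dye scaling, loess within arrays (span 0.3), quantile normalization, arrays of one scale, centring on meiosis genes, dim probes left out, excluded probes kept, the median of probes, at least 3 probes per gene, robust and trended moderation, a minimum log2 effect of 0.5, the first and last 500 bp of genes of at least 1500 bp, the residual after a linear fit on Rpb3, the partial correlation with length given occupancy, genes in more than 1 list left out, and each array left out in turn. Leaving out loci that differ between the strains, and subtracting the other strain's share of signal, were chosen after seeing the data.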

Results

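Chromatin immunoprecipitation followed by tiling microarray (ChIP-chip) was used to map 2 subunits of RNA polymerase II along the genome of the budding yeast Saccharomyces cerevisiae. Rpb3 is a subunit of the core enzyme, and Rpb4 is a subunit that pairs with Rpb7 and can leave the core. Each subunit carried a TAP tag in a strain of its own, and each group held 2 arrays, so 4 arrays were compared. The labels give the S288c background for both strains, but their extracts differed at several loci and on chromosome 9 (below), so a fully shared background is in doubt. The cells grew in rich medium (YPD) at 25 °C to an optical density of about 0.8. On every array the immunoprecipitated DNA (IP) carried the Cy5 dye and the whole-cell extract (WCE), the input DNA, carried the Cy3 dye. Occupancy is given as log2(IP/WCE) relative to the median probe of the same array, so a value of 0 is the level of the median probe and not an absence of polymerase. Values per gene are means over the probes inside the gene, with the standard error (SE) of a mean of 2 arrays. For each gene limma fitted one spread over all 4 arrays, so the SE is the same for Rpb3 and Rpb4. It is not the spread of one group, as the median difference per gene between the 2 arrays was 0.140 for Rpb3 and 0.035 for Rpb4. The number of arrays limits the precision of these values. The labels do not say that the arrays of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Of 5493 genes with a probe inside, 5490 had a value on all 4 arrays, with a median of 5 probes per gene. Across these genes the 2 Rpb4 arrays correlated at Pearson r = 0.954 and the 2 Rpb3 arrays at 0.930, while pairs of one Rpb3 and one Rpb4 array lay between 0.828 and 0.887. By rank, Rpb3 array 1 was closer to Rpb4 array 1 (Spearman rho 0.902) than to Rpb3 array 2 (0.895), whose values had the widest spread of the 4 arrays. Genes are not independent replicates, and these correlations describe the arrays.

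The first comparison asked where the core enzyme, read through Rpb3, was found in growing cells. The highest values lay over genes of fermentation, transport and amino acid synthesis. TDH3 (YGR192C, chromosome 7, probes from 883267 to 883635), which encodes a glyceraldehyde-3-phosphate dehydrogenase of glycolysis, stood at 4.33 ± 0.28 (SE, 2 arrays; limma adjusted p = 0.000567). PDR5 (YOR153W, chromosome 15, probes from 620034 to 624213), a drug efflux pump, stood at 4.27 ± 0.29. ILV5 (YLR355C, chromosome 12, probes from 838084 to 839058), an enzyme of branched-chain amino acid synthesis, reached 4.25 ± 0.17. The plasma membrane proton pump gene PMA1 (YGL008C, chromosome 7, probes from 480024 to 482570) reached 3.87 ± 0.23. The genes of highest value also included ENO2 (3.68) and PDC1 (3.67) of fermentation, the lysine synthesis gene LYS20 (3.75), the peroxiredoxin gene AHP1 (3.59), the cell wall gene CCW12 (3.52, 1 probe) and MHF1 (3.93), whose single probe lies beside ADH1. At the other end, the 6 lowest genes that passed the test lay on the mitochondrial genome, which RNA polymerase II does not transcribe, from -2.03 at AI5_ALPHA to -1.39 at OLI1, which encodes a subunit of the mitochondrial ATP synthase. The lowest nuclear genes were DPA10 (-1.18, 1 probe), PFS1 (-1.12), a gene of spore formation, the subtelomeric reading frame YFR057W (-1.10) and IRC18 (-1.10). In all, 2110 genes lay above the median probe and 1602 below it at an adjusted p of 0.05. When the arrays were centred on meiosis genes in place of all probes, the counts became 4783 and 107, because the median gene rose by 0.56.

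Of 21 gene lists tested, 18 stood apart in the Rpb3 arrays by camera with a preset correlation of 0.01, and stress, mating and the subunits of RNA polymerases I and III did not. With an estimated correlation 0 lists passed in camera, the smallest adjusted p being 0.32, and 1 list had an unadjusted p under 0.05. With only 4 arrays this form of camera could hardly pass a list. Ribosome biogenesis had an estimated correlation of -0.003, yet its unadjusted p went from 0.019 with the preset correlation to 0.118. A list that fails this form, here or below, is therefore not shown to lack a difference. Over the lists the estimated correlation ran from -0.13 (galactose) to 0.98 (glycolysis and fermentation). It was 0.25 for amino acid biosynthesis and 0.32 for ribosomal protein genes. Where the estimate is well above the preset 0.01, the camera p-values with the preset, here and below, may be far too small. The lists were fixed before the data were examined. All 127 measured ribosomal protein genes lay above the median probe, with a mean of 1.86 and array means of 1.79 and 1.93. RPS14B (3.41) and RPL10 (3.20) were highest among them and RPL23A (1.15) was lowest. Of 19 genes of glycolysis and fermentation, 18 were above, with a mean of 2.44, and the exception was the hexokinase gene HXK1 at -0.06 ± 0.08. Among 45 amino acid biosynthesis genes 39 were above (mean 1.39), and MET3 of sulfate assimilation was lowest at -0.10 ± 0.04, which did not pass. All 32 proteasome genes were above (mean 0.74), as were 14 of 15 translation factor genes (mean 1.30), with HYP2, which encodes the translation factor eIF5A, at 3.48 from 1 probe. The histone genes had 5 of 6 members above (mean 2.12), led by HHT2 at 3.35, while the linker histone gene HHO1 stood at -0.09 and did not pass. Of 24 ergosterol synthesis genes 21 were above (mean 0.70), with ERG3 at 1.52 and ERG25 at 1.32. Of 28 cell wall and membrane genes 20 were above and 4 below, from PMA1 to DAN1 (-0.82), a cell wall gene of anaerobic growth. Of 40 genes of respiration and the citric acid cycle 29 were above and 2 below (mean 0.48). Of 28 ribosome biogenesis genes 15 were above and 1, NOC3 (-0.18), was below. Of 28 chaperone genes 19 were above and 6 below, with SSA2 at 2.30 and HSP12 at -0.53.

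Lists of genes that serve other conditions lay low. Of 58 meiosis and sporulation genes 46 were below the median probe and 1 above (mean -0.48), with GAS4 of the spore wall at -0.92 and IME4, a gene of meiotic entry, above at 0.39. Of 25 genes for alternative carbon sources 19 were below and 3 above (mean -0.35), among them the lactate transporter gene JEN1 at -0.78, while the alcohol dehydrogenase gene ADH2 stood at 0.82. Of 7 galactose genes 5 were below (mean -0.31), with the transporter gene GAL2 at -0.73, and of 15 phosphate genes 8 were below and 1 above (mean -0.19). These 4 list means turned positive when the arrays were centred on meiosis genes, so the lists lay low relative to the rest of the genome only. For the meiosis list itself this centring fixed the outcome in advance. The 30 stress genes were divided, with 13 above and 11 below, from TSA1 (2.28) to GRE1 (-0.54). Of 25 mating genes 15 were above and 6 below. STE2, which encodes the alpha-factor receptor of a cells, reached 3.04 ± 0.14, and FIG1, a gene of mating, lay at -0.92 ± 0.08. By fry 20 of the 21 lists passed. Adjusted over the list alone, the member counts were the same or within 1 of these in every list with at least 5 nuclear genes. The 16 mitochondrial genes had 6 members below over all genes and 3 adjusted over the list alone.

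The second comparison asked the same of Rpb4. Rpb4 occupancy was highest over TDH3 (3.99 ± 0.28; limma adjusted p = 0.000841) and PDR5 (3.94 ± 0.29), the same 2 genes that led the Rpb3 arrays. ADH1 (YOL086C, chromosome 15, probes from 159700 to 160446), the main alcohol dehydrogenase gene of fermentation, stood at 3.67 ± 0.19, and FBA1 (YKL060C, chromosome 11, probes from 326205 to 327143), the aldolase gene of glycolysis, at 3.61 ± 0.16. ENO2 (3.56), PMA1 (3.49), CDC19 (3.32), TDH2 (3.31), GPM1 (3.31, 1 probe) and MHF1 (3.61) completed the genes of highest value, and CDC19, TDH2 and GPM1 encode enzymes of glycolysis. Among genes that passed the test, the lowest values were those of the mitochondrial gene OLI1 (-1.78, 1 probe), DPA10 (-1.09), DCV1 (-1.07) and the sporulation-specific chitin deacetylase gene CDA1 (-1.07). They were followed by the meiotic cohesin gene REC8 (-1.07), the nitrogen repressor gene DAL80 (-1.06), IRC18 (-1.06), PFS1 (-1.04), YBL044W (-1.03, 1 probe) and the hexose transporter gene HXT10 (-1.02). In all, 2079 genes lay above the median probe and 1416 below, and centring on meiosis genes made this 4749 and 99. Without Rpb4 array 1 the counts were 1072 and 313, and without Rpb4 array 2 they were 1010 and 346, where the lone Rpb4 array was assumed to vary like the Rpb3 arrays.

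By list, Rpb4 again lay above the median probe over all 127 ribosomal protein genes (mean 1.56), all 19 glycolysis and fermentation genes (mean 2.55), all 15 translation factor genes (mean 1.17) and all 32 proteasome genes (mean 0.65). RPL8A (2.76) and RPS14B (2.67) were the highest ribosomal protein genes and RPL17B (0.87) the lowest. Of 45 amino acid genes only 24 were above and 6 were below, with a mean of 0.43 and with ILV5 at 3.29 and the arginine synthesis gene ARG3 at -0.59. Of 30 stress genes 21 were above and 3 below (mean 0.69), with YGP1 at 2.06 and TSA1 at 2.03. The ergosterol list had 18 of 24 members above (mean 0.44), the histone list 5 of 6 (mean 1.82), the cell wall list 23 of 28 with 4 below (mean 1.10), the chaperone list 20 of 28 with 3 below (mean 0.80) and the respiration list 21 of 40 with 4 below (mean 0.31). Ribosome biogenesis had 14 of 28 above and 3 below. Low lists stayed low, with 47 of 58 meiosis genes, 20 of 25 alternative carbon genes and 4 of 7 galactose genes below, and 2, 2 and 0 of them above. Their means were -0.47, -0.35 and -0.38, and all 3 turned positive when the arrays were centred on meiosis genes. That centring fixes the meiosis list near 0 in advance. The phosphate list was even, with 3 members above and 3 below. Among 25 mating genes 15 were above and 8 below, with STE2 at 2.95 ± 0.14 and STE3, the a-factor receptor gene of the opposite mating type, at -0.95 ± 0.04. By camera 14 of 21 lists passed and by fry 19. With an estimated correlation 0 passed, the smallest adjusted p being 0.42, and 1 list had an unadjusted p under 0.05.

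The 2 subunits shared most of the genes they marked. Of the genes above the median probe, 1765 were shared, against 799 for independent lists of these sizes, and of the genes below it 1169 were shared, against 413. Another 43 genes lay on opposite sides. Least squares across genes gave a slope of 0.75 for Rpb4 on Rpb3, with r = 0.878, and orthogonal regression gave 0.84. The 2 Rpb3 arrays themselves differed in scale, with an orthogonal slope of 1.17 for array 2 on array 1. The orthogonal slopes of the 2 Rpb4 arrays were 0.88 and 0.93 on Rpb3 array 1, and 0.74 and 0.78 on Rpb3 array 2. The slope was thus not separated from the scale of single Rpb3 arrays. The mean difference varied with the level. In the 1098 genes with the highest mean over the 4 arrays, Rpb4 minus Rpb3 averaged -0.19, with a range over the 4 pairings of arrays from -0.28 to -0.10. In the 1098 lowest genes it averaged 0.06, with pairings from -0.003 to 0.13. Of the 138 genes lower in the Rpb4 arrays, 95 came from the highest group, as did 24 of the 51 genes that were higher. The slope was 0.88 when the arrays were brought to one scale and 0.91 after quantile normalization.

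**Figure D1:**
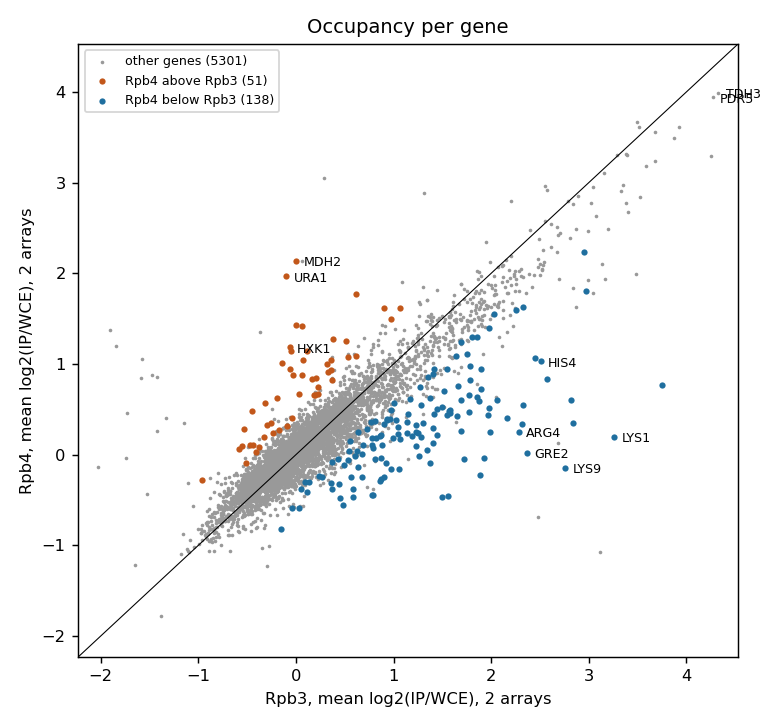
Mean log2(IP/WCE) per gene in the 2 Rpb3 arrays (horizontal axis) and the 2 Rpb4 arrays (vertical axis), with the line of equal values. The 51 genes higher and 138 genes lower in the Rpb4 arrays at an adjusted p of 0.05 (limma) are coloured, and LYS1, LYS20 and LYS9 lie farthest below the line among them.

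The comparison between the groups asked where the Rpb4 signal differed from the Rpb3 signal, which also differ in strain. Of 45 amino acid biosynthesis genes 28 had a lower IP/WCE ratio in the Rpb4 arrays than in the Rpb3 arrays, and of 30 stress genes 11 had a higher one. Each of these lists had an adjusted p = 0.43 by camera with an estimated correlation, a form that could hardly pass with 4 arrays (above). LYS1 (YIR034C, chromosome 9, probes from 419609 to 420666), which encodes the last enzyme of lysine synthesis, showed the largest decrease, at -3.06 ± 0.27 (SE of the difference, 2 against 2 arrays; limma adjusted p = 0.0199), or 8.36-fold lower. LYS20 (YDL182W, chromosome 4, probes from 133412 to 134674), which encodes homocitrate synthase, followed at -2.98 ± 0.31, with 1 of its 3 probes differing between the strains in the WCE channel, and LYS9 (YNR050C, chromosome 14, probes from 714071 to 715079) at -2.91 ± 0.19. Other genes of large decrease were ATG41 (-2.50, 1 probe), GRE2 (-2.35), a stress-inducible reductase gene, the lysine genes LYS12 (-2.22) and LYS21 (-1.98), the arginine gene ARG4 (-2.03) and MET17 (-2.01) of methionine and cysteine synthesis. MDH2 (YOL126C, chromosome 15, probes from 82055 to 82924), the cytosolic malate dehydrogenase gene, had a 4.39-fold higher ratio with Rpb4, at 2.13 ± 0.10 (limma adjusted p = 0.0108). URA1 (YKL216W, chromosome 11, probes from 25188 to 25971), a gene of pyrimidine synthesis, rose by 2.06 ± 0.08. The multidrug transporter genes PDR15 (1.42) and QDR2 (1.18), the multidrug regulator gene PDR3 (1.15), the haem-responsive activator gene HAP1 (1.36), HXK1 (1.25), the purine gene ADE17 (1.16), the cell wall gene TIP1 (1.02) and EEB1 (1.01), a gene of ethyl ester synthesis, completed the genes of largest increase. Part of these differences lay in the WCE channel, where the IP and WCE signals, as means over the probes of the gene, differed by 1.10 and -1.02 at MDH2, 1.21 and -0.84 at URA1, 0.29 and -0.88 at QDR2, -2.20 and 0.87 at LYS1, and -1.49 and 1.501 at LYS20.

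In total 51 genes were higher and 138 lower in the Rpb4 arrays, 10 and 54 of them by more than 2-fold, and 1198 genes had an unadjusted p under 0.05. Both Rpb4 arrays lay on one side of both Rpb3 arrays for all 189, which a call at this threshold already required, so it adds no support. The counts rested on the spread between arrays. Without Rpb3 array 1 they were 1843 and 1592, without Rpb3 array 2 they were 579 and 864, without Rpb4 array 1 they were 22 and 29, and without Rpb4 array 2 they were 0 and 0 (limma; 404 at an unadjusted p of 0.05).

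Of 45 amino acid biosynthesis genes 28 fell and 0 rose, and adjusted over the list alone 35 fell. The list mean was -0.96, and it was -0.83 to -1.10 over the pairings of single arrays. It passed camera (adjusted p = 1.29e-22) and fry (0.0379) but had an adjusted p = 0.43 with an estimated correlation. Besides the lysine genes, the members that fell included ARG4, MET17, LYS2 (-1.96 ± 0.13) and LEU2 (-0.97 ± 0.11). The glutamine synthetase gene GLN1 (0.59 ± 0.22) did not pass. Over the list without HIS3, which the Rpb4 strain lacked in its extract, the IP signal was lower by a mean of -0.76 and the WCE signal higher by 0.28. In 37 of these 44 genes the 2 channels moved in opposite directions, as they did in 55.6% of 5260 genes outside chromosome 9 without strain-different probes. Among the 175 of those genes that passed for the ratio, 98.3% had opposite directions, so the pattern was not particular to this list. Of 30 stress genes 11 rose and 0 fell, 13 rising when adjusted over the list alone. The list mean was 0.30, with adjusted p = 1.1e-05 by camera, 0.056 by fry and an adjusted p = 0.43 with an estimated correlation. Over 29 of these genes, without strain-different probes and outside chromosome 9, the IP signal was higher by 0.16 and the WCE signal lower by -0.15. TSL1 (0.97 ± 0.08) of trehalose synthesis, GPH1 (0.93 ± 0.06), the glycogen phosphorylase gene, and HSP12 (0.82 ± 0.09), a membrane heat shock gene, were among them. In the chaperone list HSP12 and the disaggregase gene HSP104 (0.73 ± 0.07) rose and 26 of 28 genes did not pass.

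Smaller differences ran through other lists. Of 24 ergosterol genes 4 fell, 12 adjusted over the list alone, with a mean of -0.26 (camera adjusted p = 8.71e-07 and fry 0.0379, adjusted p = 0.43 with an estimated correlation). These 4 genes, which were named after their values were seen, were ERG5 (-0.52), ERG27 (-0.44), IDI1 (-0.41) and HMG1 (-0.41). Of 127 ribosomal protein genes 126 had negative values but 2 fell, RPL7B (-0.70) and RPL40B (-0.45), also named after their values were seen. Adjusted over the list alone 52 fell and 1, RPS22B, rose. The list mean of -0.30 (camera adjusted p = 2.5e-21, fry 0.0689, adjusted p = 0.43 with an estimated correlation) became 0.05 after quantile normalization. Of 40 respiration genes CYC1 (-1.11 ± 0.13, 1 probe) of cytochrome c and RIP1 (-0.76 ± 0.06) of the cytochrome bc1 complex, which was named after its value was seen, fell, and the mean of -0.16 passed camera (adjusted p = 0.000698; adjusted p = 0.43 with an estimated correlation). The means of ribosome biogenesis (-0.07), proteasome (-0.09), the subunits of RNA polymerases I and III (-0.11) and phosphate genes (0.16) passed camera, with adjusted p from 0.0346 to 0.0419, although 0 members of these lists passed in the limma fit over all genes (the gene-wide count at an unadjusted p of 0.05 is given above). With an estimated correlation these lists had adjusted p = 0.43, 0.56, 0.43 and 0.43, and the proteasome mean turned to 0.004 with arrays of one scale and 0.05 after quantile normalization. Glycolysis, translation factors, alternative carbon, galactose, meiosis, histones, cell wall and mating genes did not pass camera, with means from -0.30 to 0.11. Single members of them did, as HXK1 and TIP1 rose, and as the spore wall gene GAS2 (0.89 ± 0.06) rose and the galactose regulator GAL3 (-0.44 ± 0.06) and the mating gene PRM5 (-0.66 ± 0.06) fell. GAL3 borders a stretch around TRP1 that the Rpb4 strain lacked in its extract. Of the 21 lists tested 10 passed camera, the mitochondrial genome being the last of them. The 4 lists that passed fry were amino acid biosynthesis, ergosterol, mating and the subunits of RNA polymerases I and III, and 0 passed camera with an estimated correlation, where 0 had an unadjusted p under 0.05.

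**Figure D2:**
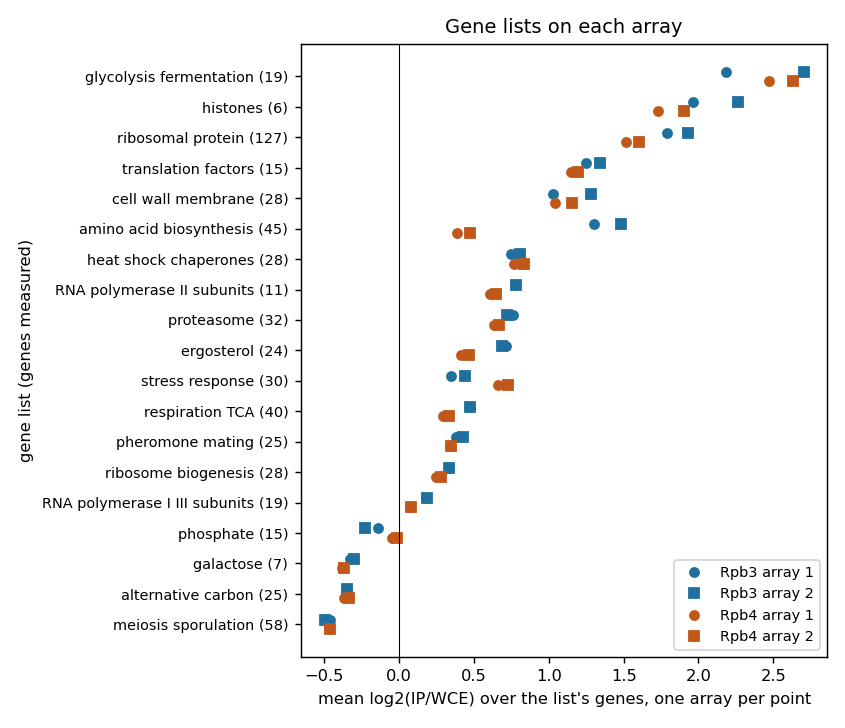
Mean log2(IP/WCE) over the genes of each fixed list, with 1 point for each array (blue for Rpb3, orange for Rpb4) and the number of measured genes beside the list's name. Amino acid biosynthesis shows the widest gap, with array means of 1.30 and 1.48 for Rpb3 and 0.39 and 0.47 for Rpb4.

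The genes of the polymerase itself were examined as a check of the strains. RPB3 (YIL021W, chromosome 9, probes from 312899 to 313699) stood at 0.89 ± 0.09 in the Rpb3 arrays and 0.47 ± 0.09 in the Rpb4 arrays, a difference of -0.42 ± 0.12 that did not pass (limma adjusted p = 0.165). RPB4 (YJL140W, chromosome 10, probes from 150655 to 151318) stood at 0.88 ± 0.06 and 0.41 ± 0.06, with a difference of -0.47 ± 0.09 (adjusted p = 0.0835). RPO21, which encodes the largest subunit, had 1.06 and 1.15, and RPB7, the partner of Rpb4, 0.41 and 0.33, and neither difference passed. Of 11 genes for RNA polymerase II subunits 9 were above the median probe in each group and 0 differed between the groups (limma), with a mean difference of -0.15 (camera adjusted p = 0.0824). Among 7 loci often used as strain markers, MET17, LYS2 and LEU2 fell, while URA3 (0.17 ± 0.13) and ADE2 (0.26 ± 0.07) did not pass. TRP1 (0.29 with Rpb3, 3.05 with Rpb4) and HIS3 (1.31 with Rpb3, 2.89 with Rpb4) also did not pass. In the Rpb4 strain the WCE signal at TRP1 and HIS3 was at most 5.97% of that in the Rpb3 strain, so their Rpb4 ratios rest on residual DNA.

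Single probes carried the comparison outside genes. At an adjusted p of 0.05 (limma), 11892 of 41563 probes lay above the array median with Rpb3 and 10323 below, and with Rpb4 10839 above and 8841 below. Between the subunits 71 probes were higher and 306 lower with Rpb4, and 5973 had an unadjusted p under 0.05. These counts depended strongly on single arrays. Without Rpb3 array 1 or 2, the counts between the subunits were 14511 and 14420 or 4650 and 7562, those for Rpb4 were 17627 and 17505 or 17632 and 17505, and those below the median for Rpb3 were 17245 or 15758. Without Rpb4 array 1 or 2, the higher counts between the subunits were 137 or 82, those for Rpb4 were 4586 and 1279 or 4546 and 1347, and those below for Rpb3 were 6652 or 6677. With genes split into parts as defined below, 58 of 3952 probes within 500 bp upstream of genes were lower and 5 higher, 27 and 0 of 3377 in divergent promoters, 81 and 12 of 9423 in the 5' part, 51 and 22 of 9397 in the middle part, and 69 and 24 of 11371 in the 3' part. With a minimum log2 effect of 0.5 no probe passed (limma treat; 1048 at an unadjusted p of 0.05).

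A further question was whether the subunits were spread differently along genes. Each gene was split into 3 parts of equal length, called the 5', middle and 3' part. Relative to the median probe of each array, Rpb3 was higher upstream of genes than Rpb4, and the 2 were close inside them. As 30279 of 41775 probes lie inside genes, the centring itself holds the 2 close there. Only the contrast between regions is thus measured. Over 3955 probes within 500 bp upstream of a start and not shared between divergent genes, Rpb3 averaged 0.43 ± 0.001 (SD, n = 2) and Rpb4 0.24 ± 0.02. Over 3378 probes of divergent promoters the means were 0.03 and -0.19. In the 5' part of genes they were -0.01 and -0.05, in the middle part 0.02 and 0.07, and in the 3' part 0.22 ± 0.002 and 0.26 ± 0.004 (SD, n = 2). Downstream of genes they were 0.42 and 0.34. The 3' part minus the upstream region was thus -0.21 ± 0.003 for Rpb3 and 0.01 ± 0.02 for Rpb4 (SD, n = 2), a difference of 0.22 with pairings from 0.21 to 0.24. These means were described and not tested. By distance from the start, Rpb4 minus Rpb3 ran from -0.22 in the last 250 bp before the gene to 0.10 between 1750 and 2000 bp into it.

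**Figure D3:**
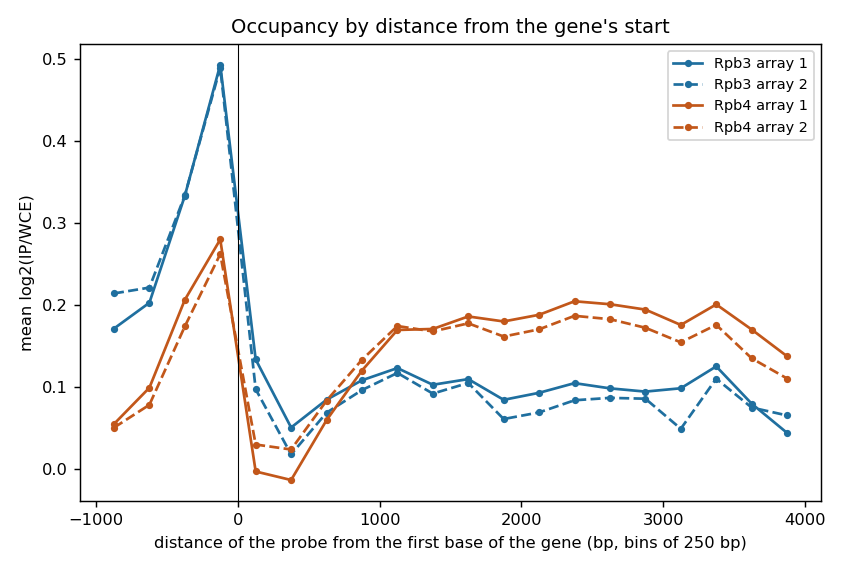
Mean log2(IP/WCE) of probes in bins of 250 bp by distance from the first base of the gene, 1 line for each array. In the bin just before the gene both Rpb3 arrays stand at 0.49 and the Rpb4 arrays at 0.28 and 0.26, and beyond 1000 bp the Rpb4 lines lie above the Rpb3 lines.

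Within single genes, the 3' part exceeded the 5' part in 1404 of 4607 genes with Rpb3 and in 1732 with Rpb4, and lay below it in 245 and 140 (limma, adjusted p of 0.05). Genes past the threshold with both subunits were ranked by the sum of their 2 values. SIW14, a phosphatase gene, showed the largest excess at the 3' end, 4.02 ± 0.37 with Rpb3 and 2.93 ± 0.37 with Rpb4. It was followed by YNG1 (3.28 and 2.66) and KTR5 (3.06 and 2.47). CTR2, a copper transporter gene, was the reverse, at -3.49 ± 0.21 and -2.44 ± 0.21, as was DFR1, the dihydrofolate reductase gene (-2.29 and -1.48). These 5 genes were chosen after their values were seen. By locus name, SIW14 (YNL032W) lies next to the histone gene HHT2 (YNL031C), which stood at 3.35 with Rpb3. CTR2 (YHR175W) lies next to ENO2 (YHR174W), at 3.68 with Rpb3. YNG1 (YOR064C) lies next to the ribosomal protein gene RPL3 (YOR063W), and KTR5 (YNL029C) next to the histone gene HHF2 (YNL030W). The differences between the ends of these genes were not separated from the signal of such neighbours. The median over genes of the 3' minus 5' value was 0.19 and 0.25 in the Rpb3 arrays and 0.31 and 0.29 in the Rpb4 arrays. No gene passed the test of the difference between the subunits (limma; 0 higher, 0 lower), and 389 had an unadjusted p under 0.05, of which 300 were higher with Rpb4. Without Rpb3 array 1 there were 1734 higher and 1342 lower, without Rpb3 array 2 there were 1026 and 213, without Rpb4 array 1 there were 3 and 2, and without Rpb4 array 2 there was 1 each way.

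The difference also followed the length of genes. Across 5490 genes, Rpb4 minus Rpb3 rose with the length tiled by probes, with Spearman rho 0.288 and Pearson r 0.210, and rho lay between 0.202 and 0.359 in the 4 pairings of arrays. The partial correlation given the mean occupancy over all arrays was 0.247. Genes are not independent replicates, and no p is given. The mean difference was -0.08 in 2271 genes under 1 kb, -0.01 in 2049 genes of 1 to 2 kb, 0.06 in 993 genes of 2 to 4 kb and 0.15 in 177 genes of 4 kb or more. At a matched position, 250 to 750 bp into the gene, these values were -0.05, -0.003, 0.004 and 0.03, so the trend with length was smaller there. The range over the 4 pairings of arrays lay on one side of 0 only in genes under 1 kb (-0.07 to -0.03). In genes of 4 kb or more it ran from -0.03 to 0.08.

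The whole-cell extracts, which serve as the reference of every ratio, also differed between the strains. Chromosome 9 gave less WCE signal in the Rpb4 arrays, with a median difference of -0.43 over 1512 probes, while the other 15 nuclear chromosomes lay between 0.02 and 0.03. The IP signal on chromosome 9 was lower as well, at -0.55. LYS1, LYS12, QDR2 and RPB3 lie on this chromosome. Outside chromosome 9, over 5260 genes without strain-different probes, the difference in WCE signal ran against the difference in IP signal (Spearman rho -0.221 across genes).

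**Figure D4:**
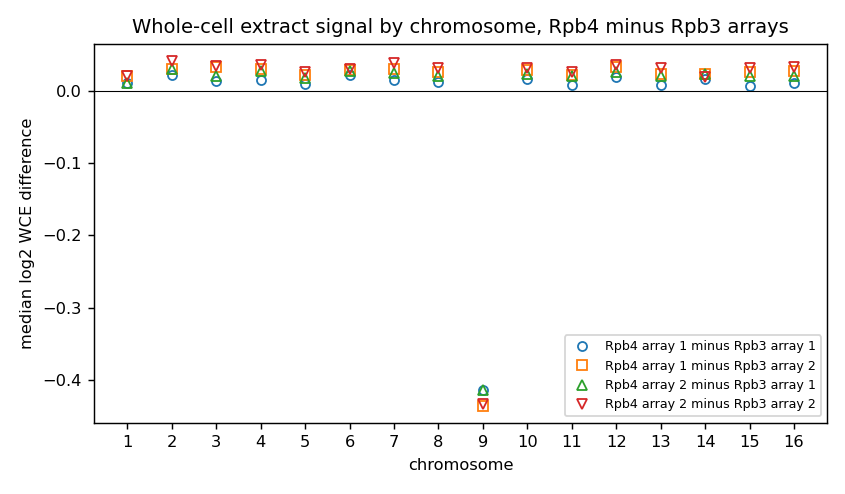
Median log2 difference in whole-cell extract signal, Rpb4 minus Rpb3 arrays, for the 16 nuclear chromosomes, with 1 symbol for each of the 4 pairings of arrays. Chromosome 9 lies between -0.44 and -0.41 in all pairings, and the other chromosomes lie just above 0.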

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

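Among the tests below, those of a single deviating array, of the direction of both channels, of different transcription, of cross-hybridisation and of DNA from the other strain were chosen after the result was seen.

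Rpb4 fell relative to Rpb3 upstream of genes compared with the 3' part of genes, by 0.22 on the log2 scale. An intensity-dependent dye effect is argued against, since 107% of the difference was left after loess within arrays. Spreading of signal from a strongly transcribed gene into its own upstream region is argued against as the whole cause. The lowest of 5 groups of genes by occupancy still showed 59.4% of the difference of the highest (0.15 against 0.25). Spreading from a strongly transcribed neighbour stays open, since upstream probes were grouped by the occupancy of their own gene and not of the neighbour. A difference of the whole-cell extracts at promoters stays open, since the WCE channel alone gave 48.6% of the difference. A lower share of Rpb4 at promoters also stays open as an untested biological explanation, because each subunit was measured in a strain of its own.

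The amino acid biosynthesis list had a mean Rpb4 minus Rpb3 difference of -0.96, with an adjusted p = 0.43 with an estimated correlation. A single deviating Rpb3 array is argued against, as the list lay at -0.87 against the nearer of the 2 Rpb3 arrays. Copy number differences were not settled by the size of the WCE difference (median 0.24 in absolute value). Fewer copies would lower both channels, however, and would largely cancel in the ratio. Over the list without HIS3, the Rpb4 arrays had a higher mean WCE signal (0.28) and a lower mean IP signal (-0.76). These means argue against fewer copies as the cause for these genes as a set. Of the list 15.9% had IP and WCE differences of the same sign, where fewer copies would lower both. The list was flagged for its IP/WCE ratio, which itself favours opposite signs. They were found in 98.3% of 175 genes that passed for the ratio, against 55.6% of 5260 genes. The count of signs is therefore no separate test of copy number. Different transcription of these genes in the 2 strains or cultures may account for the pattern, as the IP and WCE differences ran against each other across the list (Spearman rho -0.857), and the extract is not selected by either tag. This cannot be told apart from less Rpb4 per polymerase, because competition of the labelled DNAs for one probe would give the same sign (between 2 arrays of one strain, over 5260 genes, rho was -0.068 for Rpb3 and -0.022 for Rpb4) and neither subunit was measured in the other's strain.

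Signal appeared at loci that a strain lacked in its extract, in channels outside the main comparisons, and was flagged because such loci should be empty. At 6 loci missing from the Rpb3 strain, among them that of COS12 and probes beside IPP1, the IP channel of Rpb3 array 1 held a median of 12.2% of the other strain's signal and the WCE channel of Rpb3 array 2 held 7.44%. At 4 loci missing from the Rpb4 strain, among them HIS3 and TRP1, the WCE channel of Rpb4 array 1 held 4.69%. Cross-hybridisation is argued against for the loci as a set. Their median shares differed 3.86-fold (Rpb3) and 7.96-fold (Rpb4) between the 2 WCE samples of one strain, which hold the same genome. Single loci varied, from 4.75% and 8.36% in the 2 Rpb3 samples at YCL073C to 0.568% and 5.29% at that of COS12. DNA of the other strain in the sample stays open, since no locus lay more than 2.83-fold from its channel's median in the 5 channels above 2%, but loci lay up to 3.39-fold from it in the WCE channel of Rpb3 array 1 and up to 5.77-fold in the IP channel of Rpb4 array 2, and no biological explanation was tested.

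The WCE signal of chromosome 9 was lower in the Rpb4 than in the Rpb3 arrays, with a median difference of -0.43, and was flagged as a difference in the reference channel. The WCE signal of mitochondrial DNA, over 61 probes with a clear signal in the Rpb3 extracts, was lower in the Rpb4 arrays by a median of -6.36 (-2.25 over all 295 mitochondrial probes), and was flagged in the same way. Both values are approximate, since in Rpb4 array 2 only 44 of the 61 probes and 136 of the 295 lay well above background.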

How the results depend on the processing

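The settings that subtract the other strain's signal or leave out loci differing between the strains were chosen after seeing the data, and no cause of the changes below was tested except where the setting itself gives it. No paired analysis was run because the labels give no replicate numbers. Not run were the series table (the same ratios), saturated probes left out (none was saturated) and a slide block (1 slide), and the median of probes does not apply to region, probe and 3' minus 5' results. Centring on meiosis genes moved the median gene by 0.56 (Rpb3) and 0.52 (Rpb4) and gave 4783 genes above and 107 below for Rpb3, 4749 and 99 for Rpb4, 28650 and 977 probes for Rpb3, 27498 and 890 for Rpb4, and 45 and 199 for their difference. A minimum log2 effect of 0.5 gave 771 and 90 genes for Rpb3, 600 and 71 for Rpb4, 4 and 15 for the difference, 4711 and 691 probes for Rpb3, 3442 and 466 for Rpb4, and 0 and 0 for the difference (limma treat; 1048 at an unadjusted p of 0.05). For the difference, normexp gave 109 and 273 genes and 151 and 599 probes, and quantile normalization gave 189 genes above and 307 and 616 probes. At least 3 probes per gene gave 80 genes above, subtracting the other strain's signal also 80, the residual fit 56 genes below, one scale 155 probes above and loess 116 probes above. The slope on Rpb3 was 0.878 with one scale and 0.911 after quantile normalization, which also brought the correlation with length to 0.199. The 3' minus 5' median of 0.0805 became 0.122 with one scale (1 gene above), 0.114 with the first and last 500 bp, 0.115 with normexp and 0.129 with quantile normalization. The region difference of 0.223 became 0.239 with loess, 0.199 with normexp, 0.205 with quantile normalization and 0.247 after subtraction. Of the lists, 4 passed fry and 0 passed camera with an estimated correlation for the difference, where 0 had an unadjusted p under 0.05.

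Leaving out 1 array at a time, with a lone array assumed to vary like the other group, gave 0 to 1843 genes above and 0 to 1592 below for the difference (limma; 404 at an unadjusted p of 0.05 without Rpb4 array 2, the fit with 0), and 82 to 14511 and 352 to 14420 probes. For Rpb4 it gave 1010 to 2659 and 313 to 2071 genes and 4546 to 17632 and 1279 to 17505 probes, and for Rpb3 9354 to 17540 and 6652 to 17245 probes. The 3' minus 5' test gave 1 to 1734 and 1 to 1342 genes, the slope lay between 0.674 and 0.788, and 5 to 10 lists passed camera. The region difference stayed between 0.208 and 0.237 and the length correlation between 0.220 and 0.333. Signs reversed mostly through the centring on meiosis genes. For Rpb3 it moved GRE1 to 0.0190, HSP12 to 0.0340, NOC3 to 0.38 and RPC17 to 0.23, and the lists of alternative carbon to 0.21, galactose to 0.25, meiosis to 0.0814 and phosphate to 0.38. For Rpb4 it moved HSP30 to 0.29, MET17 to 0.0689, NOC3 to 0.29, RIP1 to 0.20, RPC17 to 0.0480 and TKL2 to 0.0827, and alternative carbon to 0.17, galactose to 0.15 and meiosis to 0.0583. Loess moved ICL1 to -0.0566 for Rpb3 and normexp moved HIS3 to -0.11 for Rpb4. For the difference, the proteasome mean became 0.00395 with one scale and 0.0489 with quantile normalization, and the ribosomal protein mean 0.0464 with quantile normalization. Over all settings, 4169 values of named genes kept their direction and side of the threshold, 188 lost the threshold and 158 gained it.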

Other observations

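The test of the retrograde response below was chosen after the result was seen, and the genes named in the next paragraphs were chosen after their values were seen.

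Outside the fixed lists, 36 genes were higher and 100 lower in the Rpb4 arrays. Among the lower ones, CPA1 (-1.78 ± 0.11) serves arginine synthesis, ARO3 (-1.29) and ARO4 (-1.28) encode the first enzymes of aromatic amino acid synthesis, and PCL5 (-1.30) a cyclin that promotes breakdown of the activator Gcn4. SNZ1 (-0.92) and SNO1 (-0.67) serve vitamin B6 synthesis. The nitric oxide dioxygenase gene YHB1 (-1.74) and the transporter genes ATR1 (-1.75), TPO1 (-1.28) and YOR1 (-1.11) were lower as well. So was RPN4 (-1.38), which encodes a transcription activator of proteasome genes. Among the higher genes, ADE4 (0.47) and SHM2 (0.56) serve one-carbon and purine synthesis. Some of the lower genes lie, by locus name, next to a gene of larger decrease. NRE1 (YIR035C, -1.74) lies beside LYS1 (YIR034C). INH1 (YDL181W, -1.14) and MRX19 (YDL183C, -1.06) lie on the 2 sides of LYS20 (YDL182W). Their values were not separated from the signal of that neighbour.

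Of the 43 genes above the median probe with one subunit and below it with the other, the arginine synthesis gene ARG7 stood at 0.79 with Rpb3 and -0.45 with Rpb4, and SNZ1 at 0.68 and -0.24. In the other direction, GLC3, the glycogen branching enzyme gene, stood at -0.32 and 0.19, and the repressible phosphatase gene PHO5 at -0.16 and 0.27, with an adjusted p = 0.0519 (limma) for the difference.

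A difference in copy number of the whole chromosome is a candidate explanation for the lower chromosome 9 signal in the Rpb4 extracts. If it applied, all parts of the chromosome would be shifted alike, and the 30 windows of 50 probes lay between -0.48 and -0.34, at most 0.087 from the chromosome's median. The Rpb3 signal was 1.34 times that of Rpb4, and whether the Rpb3 strain had gained or the Rpb4 strain had lost copies, in all or some cells, was not tested.

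The Rpb4 extracts held 3.06% and about 0.369% of the mitochondrial signal of the Rpb3 extracts over 61 probes chosen for a clear signal in the Rpb3 extracts, and about 30.9% and 20.1% over all 295 mitochondrial probes. In the 2 Rpb4 extracts 61 and 44 of the 61 probes, and 163 and 136 of the 295, lay well above background, so the shares over the others are not exact. The WCE signal was not lower at every gene, as OLI1 (0.36, 1 probe) and VAR1 (median over its probes 1.14) were higher in the Rpb4 arrays. A retrograde response, by which cells that lose mitochondrial DNA raise nuclear genes such as CIT2 and DLD3, was tested as a hypothesis. Neither gene was higher with Rpb4. CIT2 differed by -0.12 ± 0.16 (limma adjusted p = 0.658) and DLD3 was lower by -0.21 ± 0.06 without passing (limma adjusted p = 0.145), so the hypothesis found no support in these genes.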
